A study of Homo sapiens with 6 samples.

How the data were processed

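RNA of 6 A375 libraries, 3 given vehicle and 3 given 50 nM panobinostat for 24 h, was analysed from the table of counts deposited by the authors, whole numbers of reads per gene symbol with no normalization. Groups came from the dose in the labels, and each count column was matched to its sample by title. Per the series' design text, cells were detached with Versene and RNA was isolated on columns with a DNase step. The aligner is named only in the name of the deposited count table, as STAR. Its version, the genome build, the annotation, the library kit and the strand setting are not given in the sources used here, so no coordinates are printed, and overlapping or antisense genes cannot be separated by strand. Totals per library were 32293283 to 38944399 counts. The table held 25435 lines. Of these, 92 were spike-in controls with 0 counts, which were left out, and 25343 named genes. Among the gene lines 22597 carried a current symbol and 24187 a current or older symbol, 4353 had 0 counts in every library, and 28 carried symbols turned into dates by a spreadsheet. The date-like lines held at most 0.221% of a library's counts and were kept in the fit but not named.

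Replicates were compared before they were averaged. A chi-square statistic per degree of freedom between libraries of a group was 1.955 to 9.595, above sampling noise in each pair, and 332.8 to 381.9 between groups, and no pair was identical. The leading principal component held 95.6% of the variance and separated the groups. Genes were kept with filterByExpr of edgeR, scaled by TMM, and tested with edgeR's quasi-likelihood F test (estimateDisp, glmQLFit with robust = TRUE, glmQLFTest) on group alone. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The common biological coefficient of variation was 0.0449 and the median SE of a log2 fold change 0.0689. CPM use the TMM-scaled library sizes. Fold changes of genes with 0 counts in vehicle were bounded with a floor of 3 counts per library, and those with 1 vehicle count were given as a ratio with an exact conditional 95% interval. Intervals and floors cover counting error only. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with matplotlib 3.10.9 for the plots.

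The 37 gene lists with 747 entries, the named-gene rule, the tests of genes and lists and all alternatives but one were set before the data were examined. Of the lists 36 had at least 3 tested genes, and a list of mitochondrially encoded mRNAs was not analysed here. Lists were tested with limma's camera on log2 CPM (prior count 2) with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and also with an estimated correlation, on ranks, and with fry. Genes named were a fixed panel (measured NKG2D ligands, ADAM10, ADAM17, HLA-B, HLA-C, B2M, CD274, MITF, SOX10, CDKN1A and HDAC1), the 8 largest rises and 8 largest falls among called genes at 20 CPM or more in a group with ranges that did not overlap and no clone, noncoding, pseudogene-like or antisense symbol, up to 3 called members per direction of each list by adjusted p, the members a count needs in lists of 12 or fewer, and the 5 most abundant vehicle genes. Genes outside that rule are named only where said. Some genes that the rule takes, and 1 of the lists, are not reported here.

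The steps were tested on simulated counts for panobinostat against vehicle, drawn from the vehicle means, the fitted dispersions and the library sizes, with 200 genes changed by known folds and 14354 genes tested. edgeR recovered 68% at 1.25-fold, 96% at 1.5-fold, and 100% at 2-fold and 4-fold, and 9% of its 200 calls were genes left unchanged, above the nominal 5%. DESeq2 recovered 58%, 90%, 100% and 100%, with 7.45% of calls unchanged genes, and limma-voom 68%, 94%, 100% and 100%, with 7.65%. In simulated lists 2 of 2 moved lists and 0 of 33 unmoved lists were called by camera. Genes were drawn independently of one another, so the simulation cannot show how often camera calls unmoved lists of correlated genes. Only 200 genes were changed, in equal numbers up and down. The simulation therefore cannot show how scaling and error rates hold where most genes change. Alternatives were RLE, upper quartile and library-size scaling, no filter on low counts, a filter of 5 CPM in 3 libraries, DESeq2, limma-voom, a replicate block, leaving out each library, a test against a 2-fold change, and camera with an estimated correlation or on ranks. Thinning all libraries to the smallest total was set beforehand as a test of depth on the share of higher calls, and its use for the other results was added after the data were seen.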

Results

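A375 is an established human cell line derived from a malignant melanoma. Panobinostat is an inhibitor of histone deacetylases, the enzymes that remove acetyl groups from the lysines of histones and other proteins. A375 cells were exposed for 24 h to 50 nM panobinostat or to vehicle (the same volume of PBS), and bulk RNA was sequenced from 3 libraries of each group. Read counts per gene symbol summed to 38775631, 34738362 and 38944399 in vehicle replicates 1, 2 and 3 and to 36042161, 36201208 and 32293283 in panobinostat replicates 1, 2 and 3. At this depth 3 counts in a library correspond to 0.077 to 0.0929 CPM, the usual unit of counts scaled by library size. A count was present for 17566 to 17760 genes in the vehicle libraries and for 19100 to 19398 genes in the panobinostat libraries. Nothing in the labels says whether the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

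The comparison asked which transcripts differed between panobinostat-treated and vehicle-treated melanoma cells, among them those of MICA and MICB, the stress-induced ligands of the natural killer (NK) cell receptor NKG2D that were the subject of the laboratory's cited earlier work. Panobinostat raised MICA 2.74-fold and lowered genes of DNA replication, mitosis and homologous recombination, with 106 of 111 tested members of these 3 lists lower. Genes of MHC class II presentation fell in 12 of 12 cases, and neuronal genes rose in 30 of 31. Lysosome and autophagy genes rose in 23 of 26. Levels below are mean CPM ± SD over n = 3 libraries, and log2 fold changes are given ± SE, from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

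The response covered most expressed genes. Of 15499 genes tested, 6471 (41.8%) were higher and 6355 (41.0%) lower with panobinostat, and 2673 did not pass the threshold. At least 2-fold changes were found for 2929 genes that rose and 1815 that fell, and at least 4-fold changes for 1516 and 447. The count of genes at least 2-fold higher was 1409 when only genes at 5 CPM or more in 3 libraries were tested. The ranges of the groups did not overlap for 12930 genes (83.4%), against 10% by chance with 3 libraries in each group. The balance of rises and falls differed with level. In the eighth of genes with the lowest mean level over both groups, 59.8% rose and 13.1% fell. In the eighth at 123 CPM or more 40.2% rose and 47.1% fell. At 2-fold or more, 1023 rose and 179 fell in the lowest eighth, and 175 rose and 150 fell in the highest. The balance depends on the scaling, and the spike-in controls, with 0 counts, could not set it. With upper quartile scaling 57.3% of calls were higher, against 50.5% in the reported fit.

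**Figure D1:**
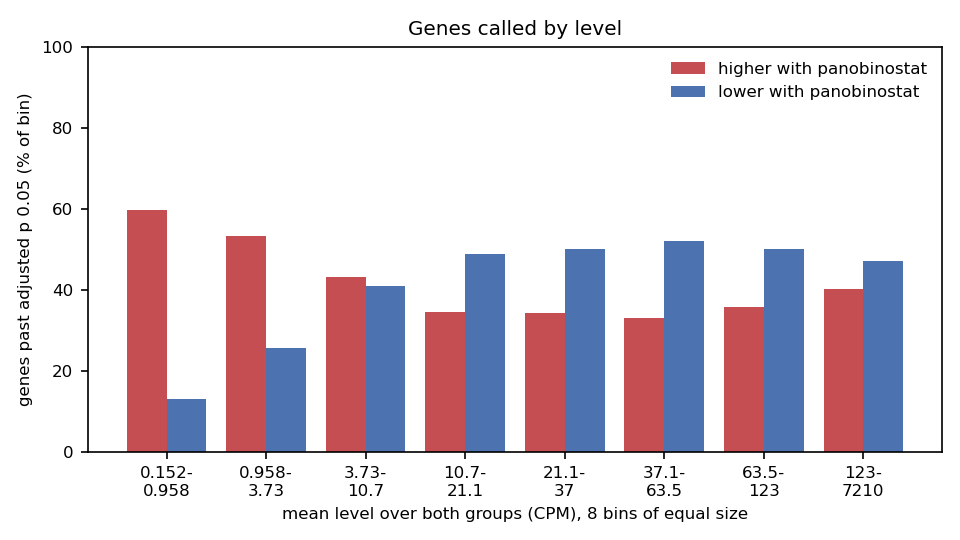
Percent of genes past an edgeR adjusted p of 0.05 and higher (red) or lower (blue) with panobinostat, in 8 bins of equal size by mean level over both groups (x axis, CPM). Genes that rose made up 59.8% of the lowest bin and 40.2% of the highest, and genes that fell 13.1% and 47.1%.

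The largest rises among genes reaching 20 CPM began from levels near 0. KRT20, an epithelial keratin, had 0 counts in the vehicle libraries and 2334 with panobinostat, at least 279-fold higher against a floor of 3 counts per library. SERPINB2, a serine protease inhibitor, S100A9, a calcium-binding protein of myeloid cells, and CREB3L3, a membrane-bound transcription factor, each had 1 vehicle count. Their ratios were 2780 (95% interval 498 to 110000), 2750 (493 to 109000) and 2610 (468 to 103000), intervals that cover counting error only. STMN2, a neuronal regulator of microtubules, rose 484-fold to 62.3 ± 1.30 CPM, and PMEL, the structural protein of melanosome fibrils, 308-fold to 194 ± 9.46 CPM. ARL14EPL rose 294-fold to 48.4 ± 0.172 CPM. The largest falls were those of SLC24A2, a sodium, calcium and potassium exchanger, from 37.7 ± 0.901 to 0.266 ± 0.0854 CPM, of the mucin MUC5B from 25.8 ± 2.67 to 0.533 ± 0.0174 CPM, and of the AP-2 transcription factor TFAP2B from 472 ± 10.8 to 11.3 ± 0.443 CPM. FXYD3, B3GNT7, KCTD15, MOK and RXRG fell as well, with log2 changes of -5.18, -4.79, -4.49, -4.46 and -4.20. Among the 5 most abundant vehicle transcripts, SERPINE2 rose from 4620 ± 62.7 to 6336 ± 46.9 CPM, and VIM, EEF1A1 and GNAS fell, with log2 changes of -0.78, -0.41 and -1.12. GAPDH, the most abundant of the 5 in vehicle, stood at 7221 ± 250 CPM in vehicle and 7194 ± 185 CPM with panobinostat, a difference that did not pass and that passed as a rise with upper quartile scaling (0.11) and with the 5 CPM filter (0.09).

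Of 36 gene lists tested, limma's camera with a preset correlation between genes put 4 higher and 9 lower than the other genes. With an estimated correlation camera called 0 lists, with 7 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0562. The rotation test fry found 34 lists moving one way on balance, a question that does not set a list against other genes. Member counts adjusted over the list alone equalled those adjusted over all genes tested in 35 of 36 lists.

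**Figure D2:**
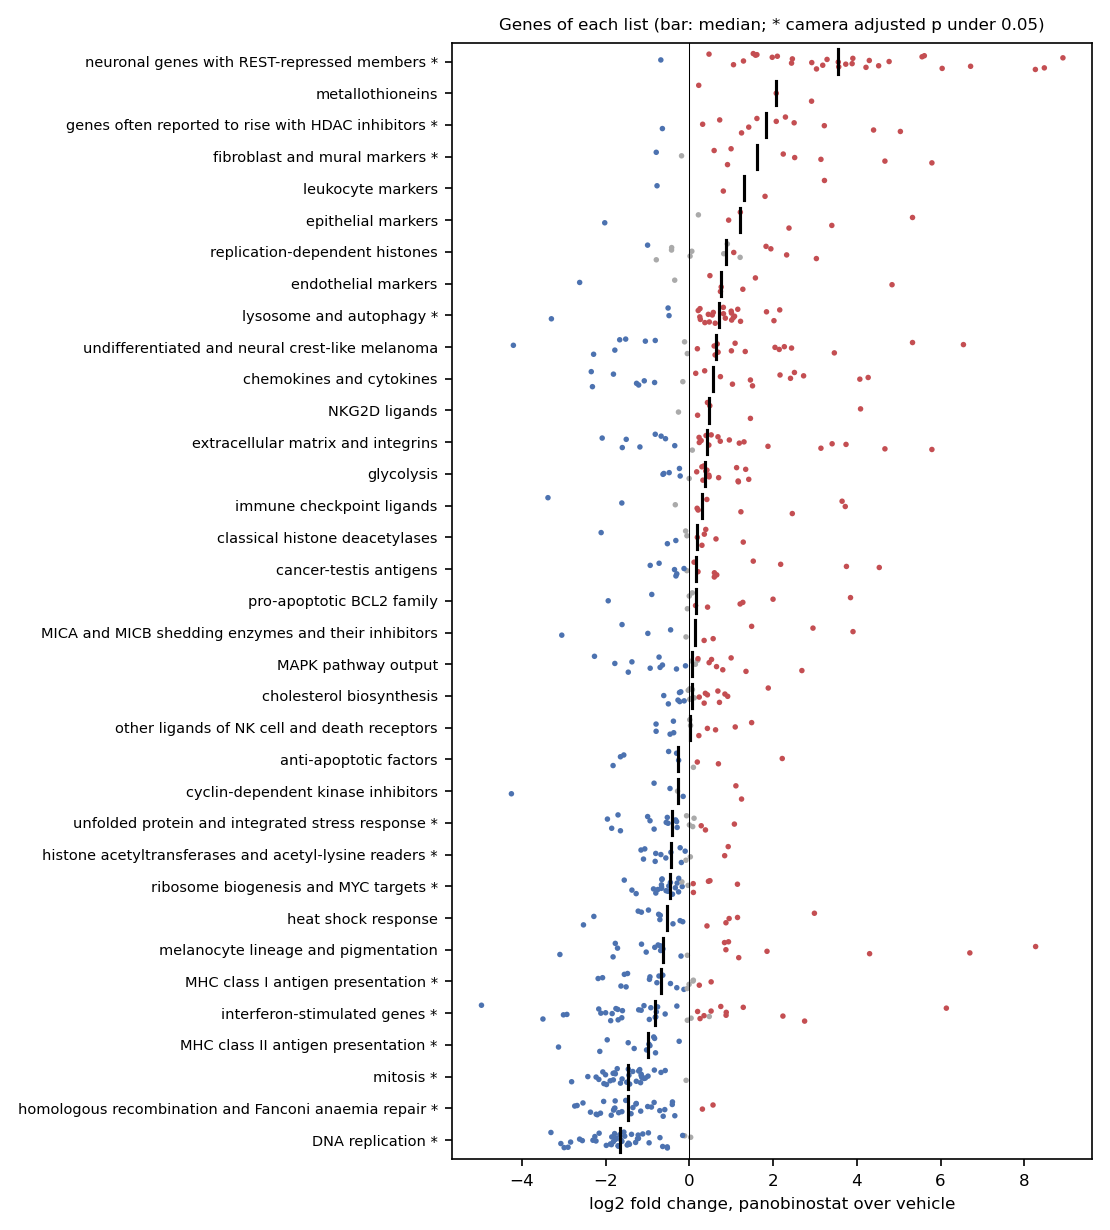
Log2 fold change (x axis, panobinostat over vehicle) of each tested member of 35 gene lists (y axis), with members that rose in red, members that fell in blue and members not past an edgeR adjusted p of 0.05 in grey. Black bars mark the list medians, from -1.65 for DNA replication to 3.55 for the neuronal list, and asterisks the 13 lists called by camera with a preset correlation.

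Ligands of NKG2D, which engage the activating receptor of NK cells, rose in 5 of 6 tested cases. MICA rose from 7.93 ± 0.503 to 21.8 ± 1.02 CPM, by 1.46 ± 0.07 on the log2 scale (edgeR adjusted p = 5.12e-12). MICB was 10.9 ± 0.144 CPM in vehicle and 12.6 ± 1.33 CPM with panobinostat, a log2 difference of 0.20 ± 0.08 (edgeR adjusted p = 0.0328). That call for MICB was lost without vehicle replicate 1 (0.17), vehicle replicate 2 (0.18), vehicle replicate 3 (0.18) or panobinostat replicate 3 (0.11), with no filter on low counts (0.15) and with a replicate block (0.19). ULBP2 rose 1.40-fold and ULBP3 1.35-fold, and RAET1G rose 17-fold from 0.0969 CPM. RAET1E stood at 2.58 ± 0.225 CPM in vehicle and 2.15 ± 0.227 CPM with panobinostat and did not pass (log2 difference -0.26 ± 0.14), although it passed without vehicle replicate 1 (-0.35). ULBP1 and RAET1L had too few counts to be tested. The list as a whole did not pass camera (adjusted p = 0.177). Proteases and inhibitors tied to the shedding of MICA and MICB moved in opposite directions, with 5 of 10 higher and 4 lower (camera adjusted p = 0.841). ADAM10 and ADAM17, metalloproteases that cleave surface proteins, rose 1.28-fold to 368.5 ± 11.1 CPM and 1.48-fold to 115 ± 0.784 CPM. The membrane protease MMP14 fell from 158.5 ± 4.80 to 19.2 ± 1.45 CPM. The metalloprotease inhibitor TIMP1 rose from 274 ± 15.9 to 2117 ± 78.1 CPM while TIMP3 fell from 1519 ± 17.8 to 498 ± 13.6 CPM. Among 12 other ligands of NK cell and death receptors, 5 rose and 5 fell (camera adjusted p = 0.966, with a median near 0 that turned below 0 in some alternatives), with PVRL2 up 2.80-fold, ICAM1 up 2.13-fold, and PVR lower by a log2 change of -0.80.

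**Figure D3:**
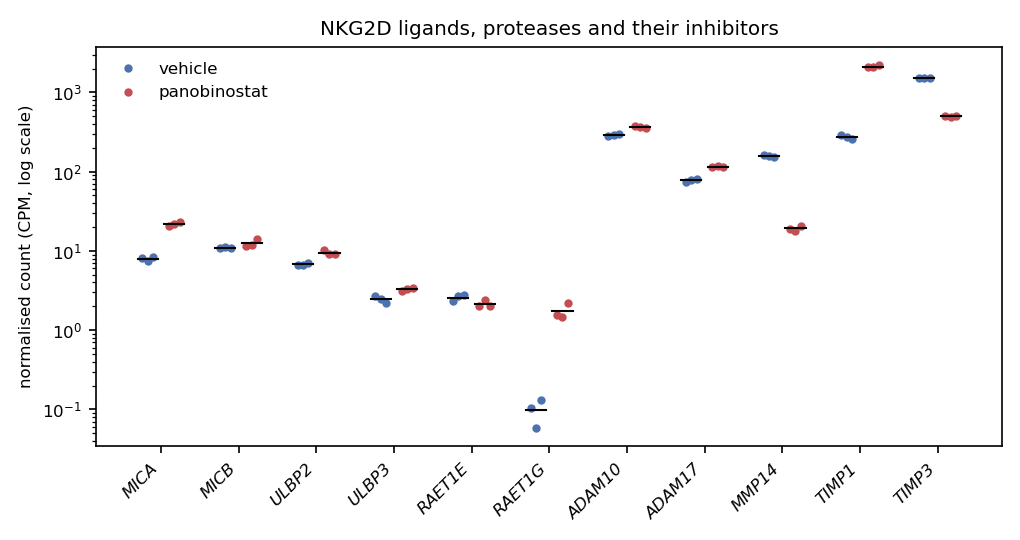
Normalised count (y axis, CPM on a log scale) of NKG2D ligands, proteases and protease inhibitors (x axis), with 1 point per library in blue for vehicle and red for panobinostat and a black bar at the mean of 3. MICA stands at 7.93 CPM in vehicle and 21.8 CPM with panobinostat, MICB at 10.9 and 12.6 CPM, and TIMP1 at 274 and 2117 CPM.

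Antigen presentation genes fell. Of 20 MHC class I genes 14 fell and 2 rose, or 13 and 4 with upper quartile scaling (camera adjusted p = 0.00752; adjusted p = 0.375 with an estimated correlation). The immunoproteasome subunit PSMB8 fell from 31.9 ± 1.02 to 7.58 ± 0.309 CPM, the peptide-trimming enzyme ERAP1 from 129.5 ± 5.50 to 45.4 ± 0.368 CPM, and the peptide-loading protein TAPBP from 77.5 ± 4.26 to 26.4 ± 0.887 CPM. Of the heavy chains, HLA-C fell from 116 ± 7.76 to 84.7 ± 4.19 CPM. HLA-B was 246 ± 9.86 and 244 ± 7.54 CPM, a difference not past the threshold that turned to a rise with upper quartile scaling (0.11). B2M, the light chain, fell by 0.13 ± 0.04 on the log2 scale, a call lost with upper quartile scaling (-0.01) and with the 5 CPM filter (-0.04). HLA genes share reads with near-identical relatives, so their values are uncertain. All 12 MHC class II genes fell (camera adjusted p = 0.00016; adjusted p = 0.375 with an estimated correlation), among them HLA-DRA from 660 ± 17.6 to 169.5 ± 10.2 CPM and HLA-DPA1 from 290 ± 4.70 to 151 ± 2.94 CPM. Interferon-stimulated genes fell in 25 of 39 cases and rose in 11 (camera adjusted p = 0.0198; adjusted p = 0.375 with an estimated correlation). IFI16, a DNA sensor, fell from 279 ± 9.59 to 91.1 ± 2.98 CPM and IFITM3 from 160 ± 8.12 to 40.0 ± 3.71 CPM, whereas BST2 rose from 2.53 ± 0.292 to 17.1 ± 1.12 CPM.

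Immune checkpoint ligands rose in 7 of 10 tested cases and fell in 2 (camera adjusted p = 0.331), or fell in 4 of 11 without panobinostat replicate 1. With the 5 CPM filter 4 were tested, of which 4 rose and 0 fell by edgeR. CD274, the ligand of PD-1, rose from 2.27 ± 0.0995 to 5.34 ± 0.731 CPM, and C10orf54 (current symbol VSIR) from 4.95 ± 0.562 to 27.2 ± 1.94 CPM. TNFRSF14 fell from 2.91 ± 0.289 to 0.274 ± 0.0495 CPM. Of 20 chemokines and cytokines 12 rose and 7 fell (camera adjusted p = 0.331), and the list's median of 0.55 turned to -0.05 with no filter on low counts. GDF15 rose 16.8-fold to 32.8 ± 0.916 CPM and IL24 4.48-fold to 211 ± 10.2 CPM, while the cytokine LIF fell by 1.81 on the log2 scale.

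Cell cycle genes fell almost throughout. Of 44 DNA replication genes 42 fell, with a median log2 change of -1.65 (camera adjusted p = 2.16e-12; adjusted p = 0.0924 with an estimated correlation). TYMS, which makes thymidylate, fell from 207 ± 8.46 to 20.9 ± 0.623 CPM, the ribonucleotide reductase subunit RRM2 from 367 ± 5.97 to 82.4 ± 2.32 CPM, and the helicase subunit MCM4 from 328 ± 9.14 to 69.9 ± 3.05 CPM. Of 35 mitosis genes 34 fell (median -1.46, camera adjusted p = 1.82e-11; adjusted p = 0.238 with an estimated correlation), among them the proliferation marker MKI67 from 868 ± 9.17 to 245.5 ± 5.84 CPM and the transcription factor FOXM1 from 149 ± 3.12 to 27.8 ± 1.46 CPM. Homologous recombination and Fanconi anaemia genes fell in 30 of 32 cases (median -1.46, camera adjusted p = 2.15e-08; adjusted p = 0.0562 with an estimated correlation), with BRCA1 down from 112 ± 3.98 to 24.0 ± 0.278 CPM. RAD51B and FANCF rose 1.48-fold and 1.24-fold. Of 7 cyclin-dependent kinase inhibitors 2 rose and 4 fell (camera adjusted p = 0.538). CDKN1A (p21) rose from 68.1 ± 4.94 to 161 ± 4.53 CPM and CDKN2D 2.16-fold, and CDKN1C (p57) fell from 16.9 ± 1.19 to 0.878 ± 0.171 CPM.

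Genes of cell death showed no common direction. Pro-apoptotic BCL2 family genes rose in 6 of 11 cases and fell in 2 (camera adjusted p = 0.331). One of these falls, that of HRK, was lost with DESeq2 and without vehicle replicate 1, panobinostat replicate 1 or panobinostat replicate 2 (-0.81, -0.82 and -0.81), which leaves 1. BMF rose 14.4-fold to 77.5 ± 1.65 CPM, BCL2L11 (BIM) 2.42-fold and BBC3 (PUMA) 2.31-fold, and BID fell by 1.94 on the log2 scale. Of 10 anti-apoptotic factors 3 rose and 6 fell (camera adjusted p = 0.509). BIRC5 (survivin) fell from 97.3 ± 2.14 to 31.1 ± 1.20 CPM and CFLAR from 20.4 ± 0.376 to 6.91 ± 0.818 CPM, whereas BCL2L1 rose 1.62-fold and BIRC3 4.65-fold.

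Melanocyte lineage genes split. Of 21 tested, 8 rose and 12 fell (camera adjusted p = 0.453, direction lower), and the median of -0.63 and the mean of 0.50 differed in sign. The median was -0.17 with no filter on low counts, and with the 5 CPM filter 3 rose and 10 fell of 14. ERBB3, a receptor kinase of the lineage, fell from 1020 ± 14.6 to 120 ± 5.53 CPM. SOX10, a neural crest transcription factor, fell from 813 ± 56.3 to 368 ± 21.8 CPM, and MITF, the melanocyte transcription factor, from 53.5 ± 2.23 to 33.2 ± 0.716 CPM. The rises included PMEL and the receptor kinase MET, from 170 ± 4.84 to 613 ± 6.0 CPM. KIT, chosen after its value was seen, had 1 vehicle count, with a ratio of 145 (95% interval 25.6 to 5780). PMEL overlaps CDK2 on the opposite strand in the reference annotation. The strand setting of the counting is not given in the sources used here, so the count of PMEL is uncertain. In vehicle, CDK2 stood at 112.7 CPM and PMEL at 0.628 CPM, so reads of CDK2 added little to PMEL there. Genes of undifferentiated and neural crest-like melanoma rose in 15 of 24 cases and fell in 7, or 8 adjusted over the list alone (camera adjusted p = 0.31). CTGF rose 11-fold to 273 ± 5.73 CPM, while the receptor kinase AXL fell from 341 ± 14.9 to 69.9 ± 3.69 CPM. Output genes of the MAPK pathway rose in 8 of 21 cases and fell in 10 (camera adjusted p = 0.841, direction lower), with a median of 0.05, which was 0.00 to 0.17 over the alternatives, and a mean of -0.11. The phosphatase gene DUSP5 rose 6.43-fold, and SPRY4, an inhibitor of the pathway, fell from 773 ± 25.6 to 161 ± 5.78 CPM.

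Genes often reported to rise with histone deacetylase inhibitors, a list drawn from general knowledge of the drug class, rose in 11 of 12 cases (camera adjusted p = 0.000504; adjusted p = 0.228 with an estimated correlation). CLU rose 32.9-fold to 142 ± 3.72 CPM, DHRS2 21.1-fold to 123 ± 2.58 CPM and TXNIP, an inhibitor of thioredoxin, from 221 ± 11.5 to 1083 ± 23.2 CPM. GSN fell from 637 ± 29.6 to 407 ± 18.6 CPM. Of 14 replication-dependent histone genes 5 rose and 1 fell (camera adjusted p = 0.327). The fall, that of HIST1H4C, was lost with DESeq2 (-0.98) and without vehicle replicate 1 (-0.63) or panobinostat replicate 1 (-0.81). Which members were tested and called varied: limma-voom found 8 rises, 5 rose and 12 fell of 32 tested with no filter on low counts, and 5 rose and 4 fell of 17 without vehicle replicate 3. The list's median of 0.86 turned to -0.88 with no filter on low counts and to -0.13 without vehicle replicate 3. It was 0.46, 0.28 and 0.38 without panobinostat replicates 1, 2 and 3, and 1.69 without vehicle replicate 1, where the list passed. HIST1H1C rose 8.18-fold to 45.8 ± 1.41 CPM. Histone genes share sequence with one another, and their counts are uncertain. Classical histone deacetylase genes rose in 6 of 11 cases and fell in 3 (camera adjusted p = 0.656). HDAC1 rose from 198 ± 3.16 to 244 ± 5.15 CPM and HDAC3 1.55-fold, and HDAC7 fell from 31.9 ± 3.06 to 7.38 ± 0.293 CPM. Acetyltransferases and acetyl-lysine readers fell in 11 of 15 cases and rose in 2 (camera adjusted p = 0.0462; adjusted p = 0.374 with an estimated correlation). That list's call was also lost with upper quartile scaling, the 5 CPM filter, a replicate block, camera on ranks, and without panobinostat replicate 2 (median -0.46). Among random lists of genes of like mean level over both groups, its median in the reported fit stood at percentile 4.93. KAT6B and BRD9 fell, with log2 changes of -1.16 and -1.10, and NCOA3 rose 1.90-fold.

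Lysosome and autophagy genes rose in 23 of 26 cases (camera adjusted p = 0.000165; adjusted p = 0.238 with an estimated correlation). The autophagy receptor SQSTM1 rose from 268 ± 8.55 to 1196 ± 7.96 CPM and the protease CTSB from 256 ± 7.87 to 1038 ± 21.8 CPM. Glycolysis genes rose in 14 of 20 cases and fell in 5 (camera adjusted p = 0.0853), with PKM, a pyruvate kinase, from 2514 ± 31.0 to 6383 ± 135 CPM and ALDOA from 1262 ± 57.1 to 2839 ± 55.2 CPM. That list passed with the 5 CPM filter. Cholesterol biosynthesis genes rose in 9 of 22 cases and fell in 7, or 14 and 3 with upper quartile scaling and 13 and 4 with the 5 CPM filter (camera adjusted p = 0.538), with STARD4 up 3.69-fold. Ribosome biogenesis and MYC target genes fell in 21 of 28 cases and rose in 5, or 3 without vehicle replicate 2, vehicle replicate 3, panobinostat replicate 1 or panobinostat replicate 3, with no filter on low counts and with a replicate block (camera adjusted p = 0.00492; adjusted p = 0.458 with an estimated correlation). NCL (nucleolin) fell from 982.5 ± 26.1 to 582.5 ± 6.65 CPM, and ODC1, which makes putrescine, rose 2.21-fold.

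Unfolded protein and integrated stress response genes fell in 13 of 20 cases and rose in 3 (camera adjusted p = 0.0325; adjusted p = 0.254 with an estimated correlation), a call also lost with the 5 CPM filter. The rises numbered 6 with upper quartile scaling and 5 with the 5 CPM filter, and the call of DNAJB9 was lost without vehicle replicate 1 (0.20). The list's median stood at percentile 3.46 among random lists of genes of like mean level over both groups. PSAT1, of serine synthesis, fell from 232.5 ± 4.58 to 59.9 ± 1.46 CPM and ASNS, the asparagine synthetase, from 130 ± 3.23 to 41.5 ± 0.511 CPM, and EDEM1 rose 2.10-fold. Heat shock genes fell in 11 of 16 cases and rose in 5 (camera adjusted p = 0.256). HSPD1, a mitochondrial chaperone, fell from 818 ± 24.4 to 369 ± 4.07 CPM, and HSPB8 rose 7.92-fold. All 3 tested metallothioneins rose (camera adjusted p = 0.189), with MT1X up 4.21-fold to 27.1 ± 1.22 CPM. MT2A moved by 0.22 on the log2 scale, and by 0.14 without vehicle replicate 3.

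Neuronal genes, including many repressed by REST outside the nervous system, rose in 30 of 31 cases with a median log2 change of 3.55 (camera adjusted p = 6.67e-10; adjusted p = 0.0562 with an estimated correlation). The median was the same, 3.55, with the member at 0 counts in vehicle set at its lower bound. With no filter on low counts 38 neuronal genes were tested, of which 33 rose and 1 fell. SYP, a synaptic vesicle protein, rose from 1.85 ± 0.294 to 90.6 ± 0.696 CPM, and SCN2A, a sodium channel, fell from 3.02 ± 0.0857 to 1.88 ± 0.296 CPM. Cancer-testis antigens rose in 9 of 16 cases and fell in 6 (camera adjusted p = 0.656), with MAGEB2 up 23.2-fold and MAGEC2 down from 163.5 ± 2.11 to 85.4 ± 2.47 CPM. Reads of these antigens can be shared between near-identical copies. Extracellular matrix and integrin genes rose in 17 of 26 cases and fell in 8 (camera adjusted p = 0.141). FN1 (fibronectin) rose from 791 ± 19.1 to 10570 ± 491 CPM and the integrin ITGA2 from 117 ± 4.73 to 1240 ± 13 CPM, while ITGB3 fell from 910 ± 18.7 to 320 ± 15.1 CPM.

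Markers of cell types other than melanoma cells were also measured. Fibroblast and mural markers rose in 8 of 10 cases and fell in 1 (camera adjusted p = 0.0325; adjusted p = 0.254 with an estimated correlation), a call also lost with upper quartile scaling and with the 5 CPM filter. COL1A1 rose from 1.0 ± 0.234 to 56.1 ± 1.57 CPM and COL1A2 from 0.0893 ± 0.0129 to 2.36 ± 0.0598 CPM, and PDGFRA fell from 10.3 ± 0.160 to 5.95 ± 0.355 CPM. Of 4 tested leukocyte markers 3 rose and 1 fell, and 6 of 14 rose with no filter on low counts (camera adjusted p = 0.31), with NCAM1, which neural cells also express, from 13.9 ± 0.570 to 130 ± 1.78 CPM. Endothelial markers rose in 6 of 8 cases and fell in 1 (camera adjusted p = 0.184), with PECAM1 up to 2.91 ± 0.293 CPM. Epithelial markers rose in 5 of 7 cases and fell in 1 (camera adjusted p = 0.0853), or fell in 2 of 8 without vehicle replicate 2 or panobinostat replicate 2. KRT18 rose from 158 ± 3.86 to 302 ± 9.0 CPM and CLDN4 from 5.36 ± 0.498 to 28.0 ± 1.03 CPM.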

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

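Thinning to equal totals, set beforehand only as a test of depth on the share of higher calls, was extended to the other results after the data were seen, and the other alternatives were chosen before. Of 205 genes taken by the rule 197 kept their direction and side of the threshold in every alternative run. So did 16 of 35 lists, all of them lists not called in the reported fit. Most of the 205 genes were chosen for a large change or a small adjusted p in these same data, which favours a high share. Each of the 13 called lists lost its call with an estimated correlation. MICA ranged from 1.39 to 1.58 on the log2 scale and passed throughout. MICB did not pass with no filter on low counts (0.1512, adjusted p = 0.0902) or with a replicate block (0.1942, adjusted p = 0.054). As single libraries were left out it ranged from 0.106 to 0.2476, and it did not pass without vehicle replicate 1 (0.1676), 2 (0.1837) or 3 (0.1795) or panobinostat replicate 3 (0.106). Its adjusted p over all alternatives, from edgeR, DESeq2 or limma, ran from 0.00154 to 0.221; the cause was not tested. The count of genes at least 2-fold higher was 1409 rather than 2929 with the filter of 5 CPM in 3 libraries, which tests 11492 genes instead of 15499. Of lists not called, the median turned below 0 with no filter on low counts for other ligands of NK cell and death receptors (-0.0262), chemokines and cytokines (-0.0469), replication-dependent histones (-0.88) and cholesterol biosynthesis (-0.00938). Camera's direction turned for MAPK pathway output with the 5 CPM filter (median 0.148) and for the other ligands with a replicate block (median 0.0175) and without vehicle replicate 1 (0.0113), 2 (0.0053) or 3 (-0.0171). As single libraries were left out, medians ranged from -0.0171 to 0.0222 for the other ligands and from -0.132 (without vehicle replicate 3) to 1.69 (without vehicle replicate 1) for the histones; the cause was not tested. With the 5 CPM filter, which leaves fewer members to test, rises and falls were 3 and 0 of 3 NKG2D ligands, 8 and 4 of 12 chemokines and cytokines, 5 and 1 of 9 pro-apoptotic genes, 20 and 0 of 20 neuronal genes, 2 and 1 of 3 endothelial and 3 and 0 of 3 epithelial markers. Camera with an estimated correlation called 0 lists rather than 13, with 7 at an unadjusted p under 0.05. Against a 2-fold change, edgeR's glmTreat called 2417 genes higher and 1439 lower.

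Upper quartile scaling moved the median log2 change of all genes from 0.00853 to 0.129, and the share of calls that were higher from 50.5% to 57.3%. HLA-B and GAPDH, both at -0.01 in the reported fit, changed sign with RLE (0.009814 and 0.0124) and library-size scaling (0.007595 and 0.01021). With upper quartile scaling HLA-B and GAPDH stood at 0.1122 and 0.1148, below the median of 0.129 over all genes. Both also changed sign with the 5 CPM filter (0.08649 and 0.08908) and DESeq2 (0.009816 and 0.0124), and GAPDH after thinning (0.004342). As single libraries were left out, HLA-B ranged from -0.05423 to 0.0111 and GAPDH from -0.04875 to 0.00537. The edgeR adjusted p of GAPDH was 0.00638 with upper quartile scaling and 0.0311 with the 5 CPM filter, and up to 0.989 over all alternatives. That of HLA-B was 0.0147 with upper quartile scaling and up to 0.972; the cause was not tested.

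No pairing of the libraries by replicate number was seen, although 3 libraries per group cannot exclude it. Deviations from the group means correlated at -0.0776, -0.0576 and -0.141 between libraries of the same number, and with the replicate block 6259 genes were higher and 6150 lower. Depth limits genes near the floor of 3 counts, such as ULBP1 and RAET1L, which were not tested.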

Other observations

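Chosen after the results were seen were the grouping of genes by symbol stem and the members named from it, the test for cells of another type, the neuronal members at 5 CPM or more and the olfactory receptors with 1 or fewer vehicle counts. The bounds for sampling noise, genomic DNA, PMEL and REST were written after the first results, among them the rise of PMEL and of genes silent in vehicle, and before the values they decide on were seen. Of 163 families sharing a symbol stem, with 10 or more tested genes each, camera with a preset correlation put 8 higher and 12 lower, and with an estimated correlation called 0 (adjusted p of 0.573 or more). The medians of the families named here kept their sign with TMM, RLE, upper quartile and library-size scaling. The families were not set against genes of like level, and 59.8% of genes in the lowest eighth by mean level rose. For CACNA, KCNJ, SYT and KRT, with many members at low vehicle level, a general rise of low genes cannot be told apart from a family pattern. Subunits of voltage-gated calcium channels (CACNA) rose in 13 of 13 cases (median 2.95, camera adjusted p = 0.00354), among them CACNA1G from 0.108 to 13.5 CPM and CACNA1H from 0.0989 to 10.2 CPM. Inward rectifier potassium channels (KCNJ) rose in 8 of 10 cases (camera adjusted p = 0.0192), with KCNJ10 from 1.80 to 11.6 CPM. Synaptotagmins (SYT), some of them also in the neuronal list, rose in 10 of 12 and fell in 1 (camera adjusted p = 0.0187), with SYT7 from 0.475 to 38.8 CPM. Keratins (KRT) rose in 13 of 17 (camera adjusted p = 0.0187), with KRT23 from 0.538 to 11.1 CPM, while KRT14 and KRT6B fell. Transcription factors of the KLF family rose in 12 of 15 cases and fell in 2 (camera adjusted p = 0.0343), with KLF4 from 8.98 to 49.3 CPM.

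Nucleoporin genes (NUP) fell in 18 of 20 cases (median -0.69, camera adjusted p = 0.000665), among them NUP188 from 207 to 84.4 CPM and NUP205 from 265 to 131 CPM. Subunits of the RNA exosome (EXOSC) fell in 10 of 10 cases, or 8 with upper quartile scaling (camera adjusted p = 0.0187), with EXOSC2 from 82.3 to 42.9 CPM. Splicing factors of the SRSF family fell in 10 of 12 cases (camera adjusted p = 0.0222), with SRSF7 from 182 to 57.9 CPM and SRSF3 from 394 to 158 CPM. PARP family genes fell in 9 of 12 cases and rose in 1 (camera adjusted p = 0.0187), with PARP14 from 85.7 to 39.8 CPM.

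The split of the 6 libraries by treatment called 12826 genes, and the highest of the other 9 splits called 0 with edgeR (2 to 84 genes at an unadjusted p under 0.05). As many genes were called in 1 of the 10 splits, which are too few for a share under 0.05. Thinning to equal totals moved the share of calls that were higher by 0.1 percentage points.

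Genes nearly silent in vehicle, with 1 count or fewer over its 3 libraries, gained 10 or more counts in every panobinostat library in 162 cases. The mirrored rule found 4 lost, a ratio of 40.5, which met the bound set against sampling noise. Both rules leave counting noise little room, so the ratio itself shows that gains outnumbered losses. Genomic DNA was to be excluded by a gain per kb of olfactory receptor genes under 10% of the median gained gene's; a first computation used all receptor reads with panobinostat instead, and its upper 95% limit of 22.4% decided nothing, with 4335 counts in vehicle and 4298 with panobinostat. The gain as the bound was written, computed after that result, had an upper limit of 2.25%, and the 344 receptors with 1 or fewer vehicle counts, which went from 9 to 93 counts, the direction of the pattern itself, had one of 0.633%. For cells of another type the bound, lenient and written with COL1A2 and PECAM1 already seen, was that no marker list reach 5 CPM in all members; the highest was the fibroblast list at 70%, with PDGFRB, ACTA2 and PDGFRA above 5 CPM in vehicle too and COL1A1 at 56.1 CPM beside COL1A2 at 2.36 and COL3A1 at 0.341 CPM. Reads running on from neighbouring genes were not tested and stay open, as does the hypothesis that the drug may act on silent genes.

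Neuronal genes rose further than genes of like vehicle level, with their median of 3.55 at percentile 100 of 10000 matched random lists, whose middle 95% ended at 1.46. For the 9 members at 5 CPM or more in vehicle the median was 1.58, against 0.404. These values argue against a general rise of low genes as the whole source. Lower expression of REST, a repressor of neuronal genes, is a candidate explanation: REST changed by -0.46 ± 0.05 (SE) on the log2 scale, between -0.5, at which it would have counted for that, and -0.25, above which against it, so the explanations cannot be told apart. Of its corepressors RCOR1, chosen after the results were seen, rose from 71.2 to 109 CPM, and an effect on REST's protein was not tested. The other lists were ranked among random lists too, matched on mean level over both groups rather than on vehicle level. Of called lists, acetyltransferases and readers (percentile 4.93) and the unfolded protein list (3.46) lay inside the middle 95%. The other called lists stood at 0.27 or lower, or at 98.3 or higher. Of lists not called, NKG2D ligands (73.9), checkpoint ligands (57.3) and histones (44.3) were among those inside. Above it lay undifferentiated and neural crest-like melanoma (100), extracellular matrix and integrins (99.6), glycolysis (99.5) and metallothioneins (98.3). Below it lay heat shock (0.73) and melanocyte genes (0.12). Medians inside cannot be told apart from those of genes of like level.

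PMEL stood at 1.98 times the level of CDK2 in the panobinostat libraries (1.91 to 2.01) and at 0.00558 times in vehicle. The ratio lies between 1, below which it would have counted for reads running on from CDK2, and 3, above which against them. The ratio takes no account of the direction in which the genes are read, so it cannot decide on reads running on. CDK2 itself fell from 112.7 to 98.1 CPM, which argues against overlap reads at their vehicle share as the source of the rise of PMEL.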
